A study of Gallus gallus with 8 samples.

How the data were processed

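Small RNA and mRNA libraries were made from the trachea of chickens (Gallus gallus) aged 42 days. Per the labels' protocols, hydrogen sulfide (H2S) gas was fed continuously into the chambers of the exposed birds, at 3.5 to 4.5 mg/kg in weeks 0 to 3 and 19.5 to 20.5 mg/kg in weeks 4 to 6, and control chambers received none. Exposed and control birds therefore lived in different chambers, and the labels name no litter, batch or day. Small RNA was sequenced from 3 H2S and 3 control samples. For mRNA, 1 H2S library and 1 control library, both numbered 3, were analysed here. The series' design text speaks of triplicates for long non-coding RNA and miRNA, and the sources used here do not say how the single mRNA column of each group relates to them. Nothing in the labels says that the samples of a group came from separate birds, so the p-values measure the spread between these samples only.

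The deposited small RNA table gives raw counts per mature miRNA, and the deposited mRNA table gives raw counts per gene together with the type of each gene. The submitters' processing notes name BWA for the small RNA libraries and HISAT2 for the mRNA libraries. Versions, genome build, annotation and the counting tool are not given in the sources used here, and neither is strandedness, so reads of overlapping or antisense genes cannot be told apart. Total counts were 15239214 to 22718151 per small RNA library over 994 mature miRNAs, and 20839798 (H2S) and 18875586 (control) for mRNA over 26296 genes. Gene symbols are those of the deposited table. Of its 11525 identifiers that begin with LOC, 521 received a symbol from a RefSeq gene table of the GRCg7b assembly, which was used for names only, and no coordinates are printed because the build of the files is not named. Identifiers without a symbol made up 17.0% of the measured genes.

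miRNA counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F-test with bias-adjusted deviance, after TMM scaling and the filterByExpr filter, which left 378 miRNAs and removed 0.0114% of the counts. p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels per library are TMM-scaled CPM, given as mean ± SD. Fixed lists of miRNAs with at least 3 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry. The test was checked on simulated counts drawn from the means and library sizes of these 6 libraries over 994 miRNAs. In simulated H2S against control comparisons, 16.8% of tested 2-fold changes and 77.5% of tested 4-fold changes were recovered, and 3.86% of calls were false. A list shifted by 1 on the log2 scale was called in 100% of 50 simulations over 378 miRNAs, and 0.462% of the other lists were called. The simulated miRNAs were drawn independently, so these list rates do not hold where members of a list vary together. In the real data the estimated correlation was 0.054, 0.25 and 0.34 in the 3 lists that camera called with the preset correlation. With 3 libraries per group, changes near 2-fold are mostly missed.

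The mRNA libraries have 1 sample per group, so no test between conditions was made, no p-value is given and no difference has a replicate check. Ratios are H2S over control of counts divided by TMM effective library sizes, with 95% exact (Clopper-Pearson) intervals from the conditional binomial distribution of the counts. These intervals cover counting error only and compare 2 libraries, not 2 conditions. A count of 0 was replaced by a floor of 3 counts in that library, and the ratio is then a bound. Genes with at least 20 counts in 1 library were measured, and ratios of at least 2 or at most 0.5 were counted. Each fixed list with at least 5 measured members is given by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Genes of a fixed list can vary together, unlike those of a random list, so a small shift of the median can give an extreme percentile. Many of the lists lay near percentile 0 or 100. On simulated counts for the H2S library against the control library over 15072 genes, the intervals held the true ratio in 94.8% of genes.

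The lists of 14 miRNA groups and 29 mRNA groups, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took every miRNA past the threshold, the 10 miRNAs with the smallest p, the 8 most abundant ones, the 2 most abundant members of each list and miR-15a. For mRNA it took the 12 highest and 12 lowest ratios among genes with at least 50 counts in 1 library, the 2 highest and 2 lowest members of each list, and the genes FOS, IL8L1, IL8L2, BCL2 and TNFAIP3. In picking the extreme ratios, 11 identifiers without a symbol were passed over at the high end and 27 at the low end. The miR-15 family list and these 5 genes were chosen from knowledge of the study's own papers and are no independent evidence. A gene that the rule took from 1 list is not reported here. Other genes named in the text were chosen after their values were seen.

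Alternatives were other scalings (median-ratio, total counts, upper-quartile), DESeq2 1.42.0, limma-voom with sample weights, the older edgeR quasi-likelihood method, other count filters, leaving out each library, a replicate block, leaving out the 5 most abundant miRNAs, other ratio limits and other expression bins. Fits with the level of miR-1a-3p or of miR-2954 as a covariate were added after the data were seen. Ratios, intervals and list percentiles were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.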

Results

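The series compared the trachea of H2S-exposed chickens with that of control birds at 42 days of age, asking which transcripts differ after exposure to this irritant gas of poultry houses. Mature miRNAs were counted in 3 H2S and 3 control small RNA libraries, with total counts of 16752529, 22718151 and 20798180 (H2S 1 to 3) and 18073175, 15288018 and 15239214 (control 1 to 3). Gene counts came from 1 H2S and 1 control mRNA library, with totals of 20839798 and 18875586. miR-148a-3p was the most abundant miRNA and took 27.5% to 43.0% of the counts of each small RNA library. The mRNA libraries were rich in transcripts of cartilage, connective tissue and striated muscle, led by COL2A1, COL3A1 and ACTA1.

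miR-202-5p, a miRNA best known from the gonads, rose in H2S trachea. Its level was 2.20 ± 0.41 CPM in H2S and 0.114 ± 0.015 CPM in control libraries (SD, n = 3 each), a log2 fold change of 4.22 (SE 0.38, edgeR quasi-likelihood adjusted p = 0.000748), and all 3 H2S libraries lay above all 3 controls. The counts behind it were small, at 28, 44 and 50 in H2S libraries and 2 in each control, and the pooled counts gave a ratio of 19.9 (95% exact interval 8.86 to 55.1, counting error only). It was the 1 miRNA of 378 tested that passed the threshold with edgeR, and 0 fell. limma-voom called 0 miRNAs and gave miR-202-5p an adjusted p of 0.0567, within a range of 9.37e-07 to 0.0567 over all alternatives that tested it.

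The 9 miRNAs that followed miR-202-5p in order of p did not pass the edgeR threshold, and each had H2S libraries that did not overlap the controls. miR-101-3p had a log2 fold change of 0.97 (SE 0.17, adjusted p = 0.104), with 6718 ± 938 CPM in H2S against 3427 ± 131 CPM in control libraries. miR-15a, whose best-known target is the survival gene BCL2, had a log2 fold change of 0.81 (adjusted p = 0.142), with 21.1 ± 1.5 against 12.1 ± 0.37 CPM. miR-199-5p and miR-217-5p had log2 fold changes of 0.75 and 1.12. On the lower side, miR-184-3p, a miRNA of surface epithelia, had a log2 fold change of -1.70 (adjusted p = 0.104), with 68.4 ± 2.7 against 222 ± 84 CPM. miR-128-3p had -0.70, miR-1560-3p -1.78, miR-1684b-3p -2.44 and miR-6546-3p -2.47, the last of these at under 1 CPM in every library. Leaving out 1 library called miR-1684b-3p lower without H2S library 1 (log2 fold change -3.46, edgeR adjusted p = 0.0353), over a range of -3.46 to -1.99 among the 6 fits, and miR-184-3p lower without control library 2 (-1.95, edgeR adjusted p = 0.00836).

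**Figure D1:**
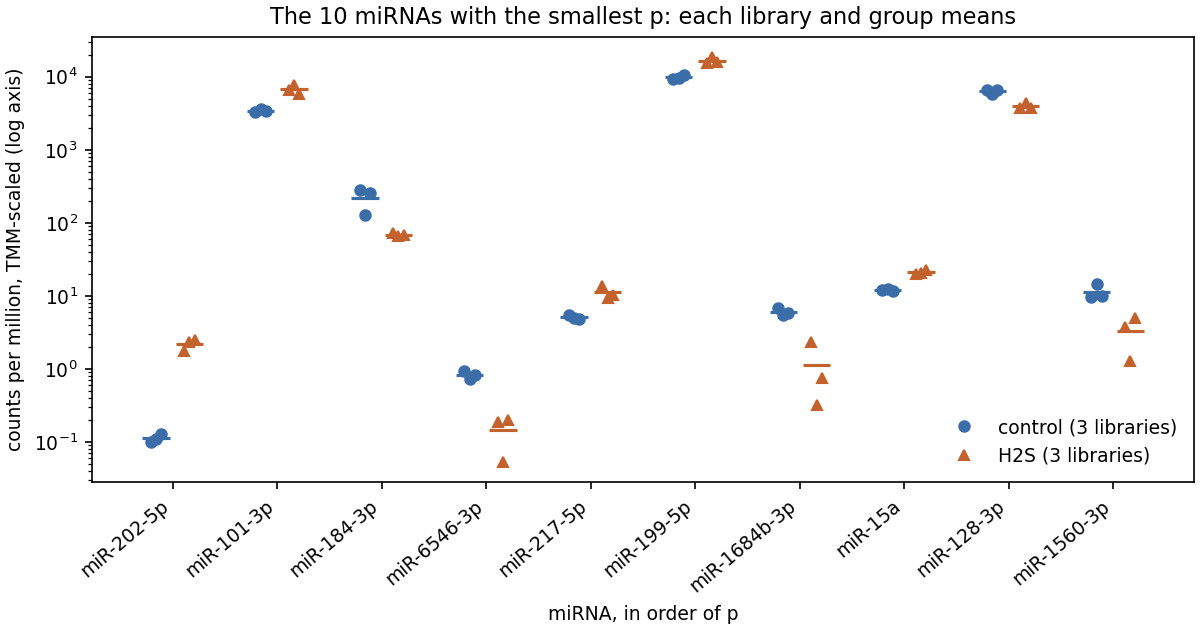
Level of the 10 miRNAs with the smallest p, in TMM-scaled CPM on a log axis, with 1 point per library (circles control, triangles H2S, n = 3 each) and a line at each group mean. The groups did not overlap for any of the 10, and only miR-202-5p (2.20 against 0.114 CPM) passed the edgeR threshold.

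DESeq2 called 10 miRNAs higher and 11 lower, among them miR-15a, miR-101-3p, miR-199-5p, miR-29c-3p and miR-202-5p on the higher side and miR-155, miR-146b-5p, miR-222a, miR-184-3p and miR-128-3p on the lower side. At an unadjusted p under 0.05, edgeR gave 32 miRNAs higher and 35 lower, where 18.9 in all would arise by chance. Other divisions of the 6 libraries into 3 and 3 gave 7 to 43 in all, the highest with H2S 1, H2S 2 and control 2 on one side. The groups did not overlap for 97 of the 378 miRNAs (25.7%), where chance gives 10% for 3 against 3 libraries. Scaling by total counts shifted the median log2 fold change of all miRNAs by -0.27 and gave 1 miRNA higher and 2 lower (miR-128-3p and miR-184-3p), with 9 higher and 66 lower at an unadjusted p under 0.05. Upper-quartile scaling shifted it by -0.16, with 13 higher and 54 lower at that level, so directions of small changes below hold for TMM scaling.

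The most abundant miRNAs did not pass the test. The cartilage miRNA miR-140-3p was at 154417 ± 21698 CPM in H2S against 104930 ± 14021 CPM in control libraries (log2 fold change 0.56, edgeR adjusted p = 0.176). miR-21-5p, a miRNA raised in many inflamed tissues, was at 25810 ± 5434 against 41123 ± 9693 CPM (log2 fold change -0.67, edgeR adjusted p = 0.227). miR-148a-3p, miR-199-3p and miR-26a-5p had log2 fold changes of 0.42, 0.31 and -0.14. let-7i and let-7a-5p were at 0.10 and -0.09, with signs that turned under other settings, and the sequence of let-7a-5p is shared with let-7j-5p, so their counts were divided between loci.

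Smooth muscle and fibroblast miRNAs were higher as a group in H2S trachea under TMM scaling, the only scaling used for the list tests. Their share of all counts overlapped between the groups, at 9.70% ± 0.51 in H2S and 9.16% ± 1.05 in control libraries (SD, n = 3). Scaling by total counts shifted the median log2 fold change of all miRNAs by -0.27. 15 of 17 measured members had a positive log2 fold change, with a median of 0.40, and camera gave an adjusted p of 0.0135 (fry adjusted p = 0.0473). The list also names miR-143 and miR-145, but no form of either was measured, so the group name rests on its other members. With an estimated correlation the adjusted p was 0.553. The fry call was lost without H2S library 1, 2 or 3 (fry adjusted p = 0.139, 0.0871 and 0.0882). It was also lost with the level of miR-1a-3p (fry adjusted p = 0.159) or miR-2954 (fry adjusted p = 0.212) as a covariate, both added after the data were seen. Adjusted over the list alone, miR-199-5p (0.75) and miR-29c-3p (1.07) were higher and miR-29b-1-5p (-1.84) was lower, while 0 of the 17 passed over all miRNAs.

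Inflammation-responsive miRNAs were lower as a group only by camera with the preset correlation (camera adjusted p = 0.019). With an estimated correlation the camera adjusted p was 0.553, and the fry adjusted p was 0.153. The median log2 fold change was -0.36, with 11 of 12 members below 0. Among the members are the -5p and -3p forms of miR-146a, miR-146b, miR-146c and miR-21, which are not independent. The members include miR-155 at -1.14 and miR-146b-5p at -0.76, both induced by NF-kB signalling, and miR-21-5p at -0.67. No member passed over all miRNAs, and 0 passed adjusted over the list alone. Of the 12 members, 11 also stand in the list of blood and immune cell miRNAs, which had a camera adjusted p of 0.0522 with 13 of 15 members below 0. The blood and immune cell list passed without H2S library 1, H2S library 2 or control library 3 (camera adjusted p = 0.0408, 0.0478 and 0.0146), with an adjusted p of 0.542, 0.540 and 0.327 with an estimated correlation. That list took 3.68% ± 0.65 of counts in H2S and 6.66% ± 1.02 in control libraries (SD, n = 3), without overlap. This share mostly follows miR-21-5p, miR-146c-5p and miR-146b-5p, at means of 33467, 8753 and 5553 CPM, and is no measure of cell numbers. Its members miR-142-3p, miR-142-5p and miR-223 were at -0.36, -0.12 and -0.27 (edgeR adjusted p = 0.645, 0.862 and 0.611). The call of the inflammation-responsive list was lost without H2S library 3 (camera adjusted p = 0.0712) and without control library 1 (camera adjusted p = 0.0512).

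Endothelial miRNAs were also lower as a group only by camera with the preset correlation (camera adjusted p = 0.0218). With an estimated correlation the camera adjusted p was 0.553, and the fry adjusted p was 0.153. The median log2 fold change was -0.37, with 9 of 11 members below 0. Adjusted over the list alone, miR-222a (-1.13), miR-222b-5p (-1.28) and miR-222b-3p (-1.24) were lower, and 0 members passed over all miRNAs. miR-222 is also made by many dividing cells, and miR-126-3p, the most abundant member and the one most restricted to endothelium, was at 0.05 and turned to -0.21 with total counts and -0.12 with upper-quartile scaling. This call too was lost without H2S library 3 (camera adjusted p = 0.0595) and without control library 1 (camera adjusted p = 0.0878).

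The remaining lists did not pass the test with camera. In the miR-15/16 family, chosen from the study's own papers and so no independent evidence, 7 of 9 members were above 0 with a median of 0.21 (camera adjusted p = 0.159), and miR-15a alone was higher when adjusted over the list alone. miR-16c-5p and miR-16-5p were at 0.21 and 0.14 and turned to -0.05 and -0.14 with total counts. In epithelial miRNAs, 7 of 11 members were below 0 (camera adjusted p = 0.177), and miR-184-3p was lower when adjusted over the list alone. miR-200b-3p and miR-200a-3p, which mark epithelium, were at 0.12 and 0.43. Hypoxia and p53 miRNAs had a median of 0.42 (camera adjusted p = 0.0522). They passed without H2S library 1 or 3 (camera adjusted p = 0.0408 and 0.0428, adjusted p = 0.542 and 0.619 with an estimated correlation). Of their 7 measured members, 4 were forms of miR-34b and miR-34c that also stand in the multiciliated list, and no form of miR-210 was measured. Multiciliated cell miRNAs had a median of -0.18 (camera adjusted p = 0.843), although their 2 most abundant members, miR-34b-5p and miR-34c-5p, were at 0.72 and 0.64 without overlap between the groups. The direction of this list in camera turned to higher without H2S library 1, H2S library 3, control library 1 or control library 3 (camera adjusted p = 0.492 to 0.933).

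Erythroid miRNAs had a median of 1.19 over 3 members (camera adjusted p = 0.126), with miR-451 at 1.24 and miR-144-3p at 1.19. Without control library 2 miR-144-3p was at 1.83 (edgeR adjusted p = 0.151), and leaving out 1 library gave ranges of 0.686 to 1.83 for it and 0.714 to 1.70 for miR-451. The let-7 family had a median of -0.09 (camera adjusted p = 0.109) and passed without H2S library 2 (camera adjusted p = 0.0279, adjusted p = 0.540 with an estimated correlation). The median was -0.05 in the miR-17-92 clusters (camera adjusted p = 0.159), with miR-92-3p at -0.32 and miR-20a-5p at 0.05. Cartilage miRNAs had a median of 0.18 (camera adjusted p = 0.307), and miR-140-5p was at 0.03. In neuroendocrine and thyroid miRNAs the median was -0.05 and the mean 0.12 (camera adjusted p = 0.317), with miR-375 at 0.57 and miR-7 at -0.20. Skeletal muscle miRNAs had a median of 0.28 (camera adjusted p = 0.307), with miR-1a-3p at 0.22 and miR-499-5p at 0.28. This list turned to lower without control library 2 (camera adjusted p = 0.310) and passed as higher without H2S library 2 (camera adjusted p = 0.0472, adjusted p = 0.540 with an estimated correlation). Adjusted over each list alone, 0 members of these last 6 lists, of the multiciliated list, of the hypoxia and p53 list or of the blood and immune cell list passed.

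The amount of muscle RNA differed between libraries of the same group. Skeletal muscle miRNAs took 9.56%, 4.60% and 14.3% of counts in H2S libraries 1 to 3 and 14.96%, 2.18% and 11.03% in control libraries 1 to 3. With the level of miR-1a-3p as a covariate, added after the data were seen, miR-202-5p was again higher and miR-184-3p was lower (log2 fold change -1.79, edgeR adjusted p = 0.0175). Cartilage miRNAs took 14.98% ± 1.69 of counts in H2S and 12.6% ± 1.9 in control libraries.

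**Figure D2:**
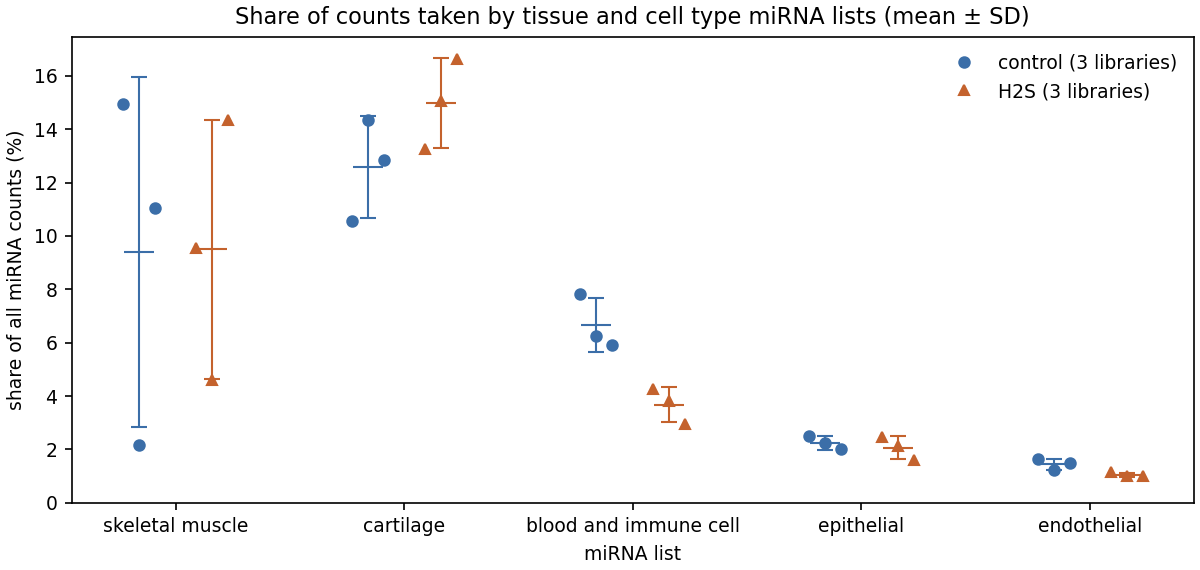
Share of all miRNA counts (percent, linear axis) taken by 5 miRNA lists, with 1 point per library (circles control, triangles H2S, n = 3 each) and bars at mean ± SD. Skeletal muscle miRNAs ranged from 2.18% to 14.96% among control libraries. Blood and immune cell miRNAs, of which miR-21-5p was the most abundant, lay at 3.68% in H2S and 6.66% in control libraries on average.

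The mRNA comparison rests on 1 library per group and describes those 2 libraries. The H2S library had far higher counts of interferon-stimulated genes, the antiviral programme switched on by type I interferon. Of 37 measured members, 28 were at least 2-fold higher and 2 at least 2-fold lower, and the median ratio was 3.90 (log2 1.97, percentile 100 among matched random lists). RSAD2, which encodes viperin, was 64.6-fold higher (59.7 to 70.0, counting interval), from 42638 against 619 counts. IFIT5 was 32.9-fold higher (31.2 to 34.7), HELZ2 15.6-fold and OASL 13.2-fold. The interferon gene IFNB had 81 counts in the H2S library and 0 in the control library, at least 25.3-fold higher over a 3-count floor.

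Among other members of the list, named after their values were seen, the RNA sensor IFIH1 was 10.3-fold higher, the kinase EIF2AK2 7.24-fold, MX1 6.37-fold and the transcription factor IRF7 4.89-fold. Outside the list, the RNA sensor TLR3 was 3.39-fold higher and the RNA sensor TLR7 had a ratio of 1.32 (1.20 to 1.46), also named after their values were seen. The interferon genes IFNL3 and IFNA3 had 3 against 0 counts and 0 counts in both libraries, too few to compare. The 5 members below a ratio of 1 belong to class I antigen presentation, which interferon usually raises. BF2 was 4.24-fold lower (4.10 to 4.39) and B2M 2.16-fold lower, and BF1, TAP2 and TAP1 had ratios of 0.727, 0.770 and 0.932. Another 4 members, UBA7, IRF8, GBP and LY6E, had ratios of 1.09 to 1.34. GBP7, which is outside the list but belongs to a family of interferon-inducible GTPases, had 0 against 167 counts, at least 59.4-fold lower. BF1 and BF2 are near-identical class I genes of a polymorphic locus, so the division of reads between them is uncertain. IFNG had 18 and 15 counts, a ratio of 1.12 (0.536 to 2.40), so a difference was not detectable at this depth.

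**Figure D3:**
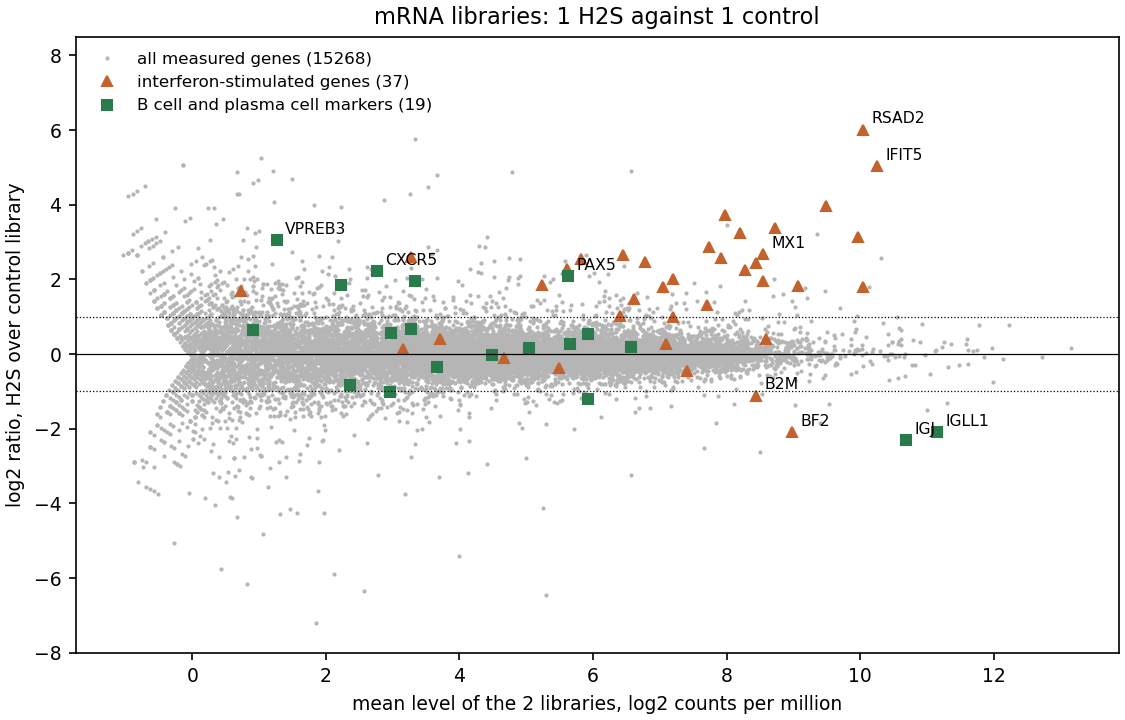
Log2 ratio of the H2S over the control mRNA library against the mean level of both (log2 CPM), with 1 point per gene with at least 20 counts in 1 library, interferon-stimulated genes as triangles and B cell and plasma cell markers as squares and dotted lines at 2-fold ratios. RSAD2 lies at 6.01 and IFIT5 at 5.04, and IGJ at -2.31.

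The list of inflammatory cytokines and NF-kB response genes had a median log2 ratio of 0.39 (percentile 100). Of its 43 measured members, 26 were within 2-fold, 14 were at least 2-fold higher and 3 at least 2-fold lower in the H2S library, and 14 of the 43 had ratios below 1. SOCS1, a brake on cytokine signalling, was 7.40-fold higher (5.94 to 9.32), and the chemokine CCL4 7.33-fold (5.92 to 9.16). At the other end, IL22 had a ratio of 0.245 from 6 against 23 counts, and AVD, which encodes avidin, one of 0.251 (0.225 to 0.279). Of the genes that the study's own papers name, which are no independent evidence, the chicken interleukin-8 genes IL8L2 and IL8L1 were 6.70-fold (3.81 to 12.7) and 5.16-fold (2.76 to 10.5) higher. TNFAIP3 had a ratio of 1.44, BCL2 1.18 and FOS 0.642 (0.599 to 0.688). The median log2 ratio over these 5 genes was 0.53 (percentile 98.8).

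Members of the B cell and plasma cell list went both ways. IGJ, the joining chain of secreted antibody, was 4.95-fold lower (4.85 to 5.05) and the light chain gene IGLL1 4.25-fold lower (4.18 to 4.32), from 70789 counts in the control library. VPREB3 was 8.25-fold higher (4.28 to 17.8) and CXCR5 4.67-fold higher (3.39 to 6.56). PAX5, IRF4, TNFRSF13B and POU2AF1, named after their values were seen, had ratios of 4.26, 0.432, 0.495 and 1.11. Over the 19 measured B cell and plasma cell markers, 5 were at least 2-fold higher and 4 lower, so the median log2 ratio of 0.27 (percentile 99.6) joins members that went both ways. Immunoglobulin genes belong to families of similar sequence, so their single counts are uncertain.

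T cell markers had a median log2 ratio of -0.29 (percentile 0.13), with 5 of 33 members at least 2-fold lower, among them CTLA4 (ratio 0.307) and XCL1 (0.330), and with GATA3 at 1.99 and IL2RA at 1.68. Macrophage, dendritic cell and heterophil markers had a median of -0.16 (percentile 2.43). MMP7 was 5.70-fold lower (5.37 to 6.07) and FLT3 had a ratio of 0.345, while TIMD4 was 3.24-fold higher and SERPINB10 had a ratio of 1.89.

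Multiciliated cell markers were slightly lower in the H2S library, with a median log2 ratio of -0.20 (percentile 0.02). Of 48 members, 38 were below 0 and 0 were beyond 2-fold, and WDR63 and WDR16 were lowest at ratios of 0.598 and 0.602. CCNO and DYNLRB2 were highest at 1.68 and 1.30, from under 50 counts each. Secretory and mucous cell markers had a median of -0.26 (percentile 0.09), with 6 of 25 members at least 2-fold lower and 2 higher, and a median of -0.028 among members with at least 100 counts in 1 library. MUC4 and AGR3 had ratios of 0.176 and 0.180 from low counts, while MUC13 was 3.07-fold higher (2.96 to 3.17) and FCGBP 3.15-fold. Basal and squamous markers had a median of -0.06 (percentile 14.1), inside the range of matched random lists, with TP63 and ANXA8 at 0.490 and 0.573 and KRT14 and PKP1 at 2.29 and 1.97.

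Cartilage, skeletal muscle and ribosomal protein groups were higher in the H2S library. Cartilage markers had a median log2 ratio of 0.42 (percentile 100) with 24 of 27 members above 0, EPYC and MATN3 at 2.75-fold and 2.63-fold, and LECT2 and COL10A1 at ratios of 0.339 and 0.441. Skeletal muscle markers had a median of 0.32 (percentile 100), with the myosin heavy chain genes MYH1C and MYH1A 4.00-fold and 3.49-fold higher and CKMT2 and MYL2 at 0.368 and 0.565. The myosin heavy chain genes form a cluster of close copies, so their single counts are uncertain. Ribosomal protein genes had a median of 0.32 (percentile 100) with 68 of 75 members above 0, from RPS20 and RPL37 at 0.903 and 0.935 to RPL23 and RPS27A at 2.05 and 2.04.

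Stress and metabolic groups had medians closer to 0. In hydrogen sulfide and sulfur metabolism the median was -0.23 (percentile 1.31) with 0 of 15 members beyond 2-fold under TMM scaling. ETHE1, a mitochondrial enzyme of sulfide oxidation, had a ratio of 0.513 (0.382 to 0.683) and passed the 2-fold limit with total counts. MAT1A had a ratio of 0.541, CDO1 1.07, and CBS, which can make H2S, 1.58 (1.48 to 1.69). Nuclear cytochrome c oxidase genes, which encode subunits, assembly factors and related proteins of the enzyme that H2S inhibits, had a median of -0.19 (percentile 2.90). Their ratios ran from COX7C and COA6 at 0.624 and 0.680 to COX18 and COX17 at 1.34 and 1.23. The other nuclear oxidative phosphorylation genes had -0.16 (percentile 0.16), with NDUFA6 and ATP5S at 0.510 and 0.566 and ATP5E and NDUFA2 at 1.40 and 1.31. The 13 mitochondrially encoded genes in the table had 0 counts in both libraries and could not be compared. Whether they were part of the reference used for counting is not given in the sources used here.

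Antioxidant and NRF2 target genes had a median of -0.16 (percentile 0.12). The cystine transporter gene SLC7A11 was 2.84-fold higher (2.46 to 3.28) and SRXN1 had a ratio of 1.57, while BLVRA was 3.94-fold lower (3.43 to 4.54) and AKR1D1 had a ratio of 0.573. Heat shock and chaperone genes had a median of 0.11 (percentile 95.4), with the small heat shock gene HSP25 4.82-fold and HSPH1 2.35-fold higher and HSPB7 and HSPA13 at 0.5004 and 0.640. Apoptosis and necroptosis genes had a median of 0.13 (percentile 99.0), with the pro-apoptotic gene PMAIP1 4.01-fold and BIRC2 2.92-fold higher and BIRC7 and CASP18 at 0.447 and 0.605. Immediate-early genes had a median of -0.20 (percentile 0.29), with NR4A2 and NR4A3 3.24-fold and 2.10-fold lower, ATF3 2.28-fold higher and GADD45B at 1.95.

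Proliferation genes had a median of -0.24, below all matched random lists, with 50 of 60 members below 0, ANLN and RACGAP1 at 0.407 and 0.525 and CDC6 and CDCA7 at 1.98 and 1.82. Adipocyte and fatty acid genes had a median of -0.12 (percentile 2.70), with FABP3 and DGAT2 at 0.532 and 0.660 and PLIN1 and PPARG at 1.72 and 1.71. Hypoxia and glycolysis genes had -0.05 (percentile 11.4), with MXI1 and PFKP 2.90-fold and 2.14-fold higher and PGAM1 at 0.702. Smooth muscle markers had 0.05 (percentile 71.1), from PLN and PGM5 at 0.593 and 0.727 to LMOD1 and TPM1 at 2.32 and 1.63. Fibroblast and extracellular matrix genes had 0.07 (percentile 80), from POSTN and MFAP5 at 0.666 and 0.729 to COL8A1 and TIMP2 at 1.46 and 1.44.

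Endothelial markers had a median log2 ratio of 0.01 (percentile 60.9), which turned to -0.04 with total counts, with CLDN5 and VWF at ratios of 0.774 and 0.808 and NOS3 and ENG at 1.52 and 1.45. Erythrocyte markers had 0.20 (percentile 93.8), with TFRC and EPB41 at 0.607 and 0.736 and H1F0 and LMO2 5.29-fold and 2.23-fold higher. Nerve markers had 0.22 (percentile 86.5), with UCHL1 and SYT1 at 0.743 and 0.959 and NEFH and STMN2 at 4.13 and 1.65 from at most 30 counts. Thyroid and parathyroid markers had -0.28 (percentile 7.63), with DUOX2 and NKX2-1 at 0.586 and 0.631 and SLC26A4 and SLC5A5 at 1.56 and 1.13.

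**Figure D4:**
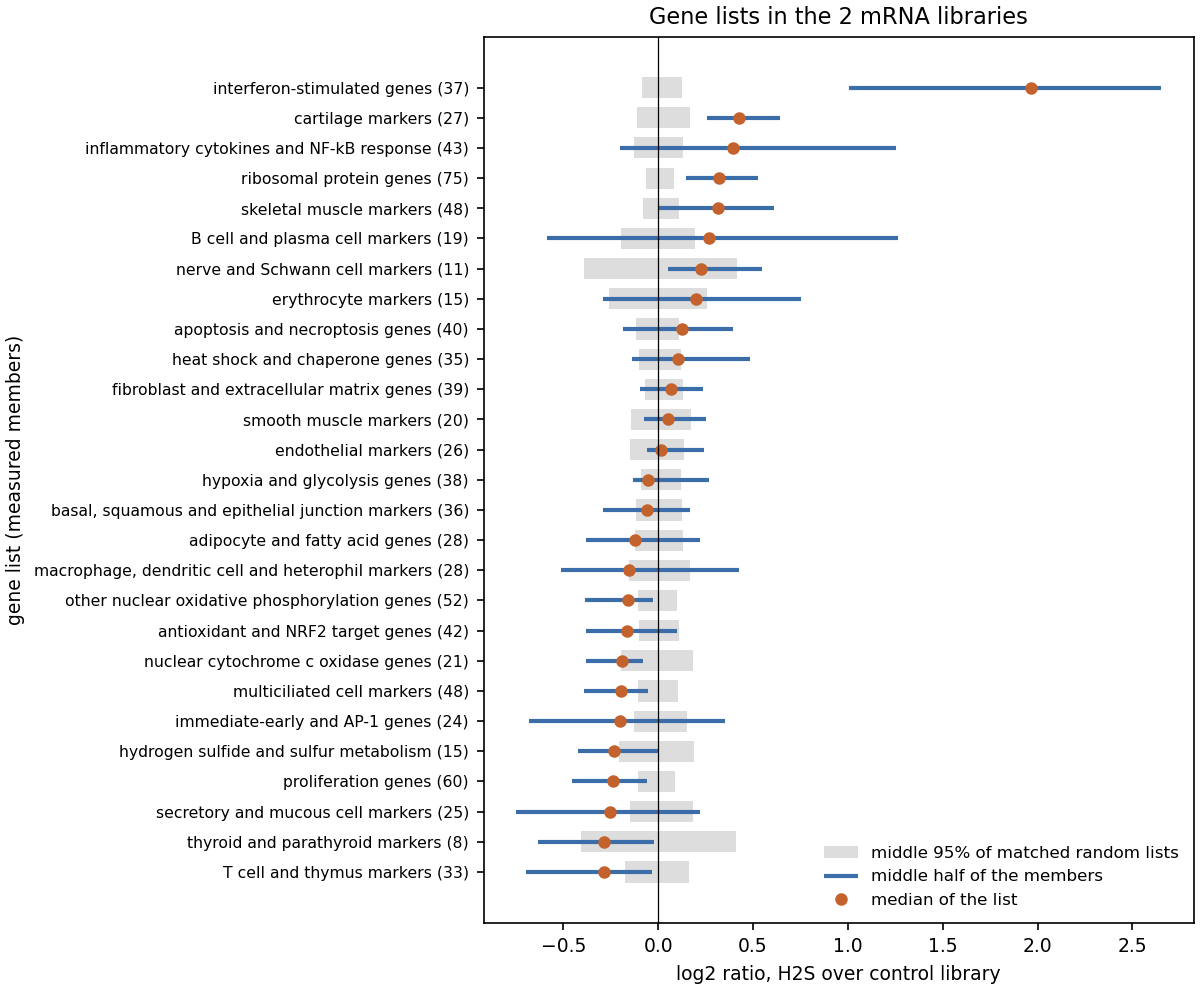
Median log2 ratio (points) of each gene list in the H2S over the control mRNA library, with the quartiles of its members (line ends) and the middle 95% of 10000 matched random lists (grey), and the number of measured members in parentheses. Interferon-stimulated genes lie at 1.97, cartilage markers at 0.42 and T cell markers at -0.29.

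Outside the lists, the highest ratios included LYGL (LOC418700 in the files), a goose-type lysozyme-like gene, at 29.8-fold (24.8 to 36.1), the surfactant protein gene SFTPA1 at 29.4-fold (21.01 to 42.4) and the water channel gene AQP2 at 26.0-fold from 111 against 4 counts. HIST1H46L6, SRRM4, MRPS34 and TUBA8B were 17.6-fold, 16.9-fold, 15.9-fold and 12.2-fold higher. The lowest ratios included all 3 fibrinogen chain genes, with FGG 42.3-fold lower (25.4 to 76.0), FGB 17.4-fold lower (13.9 to 21.9) and FGA 10.7-fold lower (4.28 to 34.3), and VTN, another plasma protein gene, 6.89-fold lower. CRISP2 had 1 against 138 counts, a ratio of 0.0068 (0.000171 to 0.0385). The immunoglobulin genes VH26L8 and VH26L2 were 11.9-fold and 7.25-fold lower, and FUT9, ATP13A5, TCF24 and CRYBB2 9.12-fold, 8.89-fold, 8.53-fold and 8.21-fold lower.

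In all, 719 of 15268 measured genes were at least 2-fold higher and 566 at least 2-fold lower in the H2S library, and 90% of the log2 ratios lay between -0.84 and 0.97. Protein-coding genes made up 530 of the higher and 421 of the lower ones, or 3.87% and 3.07% of the 13696 measured. Long non-coding RNAs made up 168 and 126, or 12.95% and 9.71% of the 1297 measured. They took 1.03% of all counts in the H2S and 1.06% in the control library. Counting error alone takes more genes with few counts past 2-fold, and the shares were not compared at equal counts. With a limit of 4-fold the counts were 181 and 130, and with at least 5 counts in 1 library they were 1331 and 1177.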

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

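The covariate fits were chosen after the data were seen and the other alternatives before. For miRNAs, 1 was called higher under every scaling, filter and left-out library, and the call was miR-202-5p except with the filter of at least 10 CPM, which removes it and called miR-101-3p. DESeq2 called 10 higher and 11 lower (47 adjusted p-values were not given by it), and limma-voom 0 and 0. The count of lower miRNAs was 2 with total counts, 1 with the 10 CPM filter (miR-128-3p), 1 with the miR-1a-3p covariate and 0 to 1 when a library was left out (miR-1684b-3p without H2S 1, miR-1682 without H2S 3, miR-184-3p without control 2). The number of lists past the threshold, 3 with camera, was 0 with an estimated correlation, 1 with fry, 5 with the miR-2954 covariate (adjusted p = 0.608 for each of the 5 with an estimated correlation) and 1 to 6 when a library was left out, with 5 without H2S 1, 6 without H2S 2 and 1 without control 1. The cause was not tested.

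The replicate numbers did not pair the libraries: deviations from the group means correlated by -0.31, 0.08 and 0.27 between same-numbered libraries across 378 miRNAs, and not every library correlated best with its own number. The replicate block gave 1 miRNA higher and 0 lower, and 5 lists, adding the blood and immune cell list (camera adjusted p = 0.0389) and the erythroid list (camera adjusted p = 0.0143). With an estimated correlation under the block, the adjusted p was 0.417 for both, and 0.417 to 0.528 over all 5. With fry, the block ended the call of the smooth muscle and fibroblast list (fry adjusted p = 0.0956) and called the erythroid list (fry adjusted p = 0.0133). It changed no other call of these tests. With either covariate fry called 0 lists, and without H2S 1 it called the miR-17-92 list (fry adjusted p = 0.018), whose camera adjusted p was then 0.148. No paired analysis was possible for mRNA because each group has 1 library.

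Named miRNAs that turned direction did so for 32 of 638 values, with at most 0.25 in log2 fold change and none past the threshold. With total counts these were let-7i (-0.17), miR-16c-5p (-0.053), miR-16-5p (-0.14), miR-200b-3p (-0.15), miR-140-5p (-0.25), miR-126-3p (-0.21) and miR-20a-5p (-0.21). With upper-quartile scaling they were let-7i (-0.067), miR-16-5p (-0.017), miR-200b-3p (-0.052), miR-140-5p (-0.13), miR-126-3p (-0.12) and miR-20a-5p (-0.099). Without the 5 most abundant miRNAs, let-7i was at -0.0041, miR-140-5p at -0.052, miR-126-3p at -0.053 and miR-20a-5p at -0.046. With limma-voom let-7a-5p was at 0.015 and miR-126-3p at -0.016. With the 10 CPM filter miR-140-5p was at -0.022, and with the miR-1a-3p covariate miR-20a-5p was at -0.0095. Leaving out a library gave ranges of -0.19 to 0.70 for miR-1a-3p, -0.0081 to 0.21 for let-7i, -0.28 to 0.040 for let-7a-5p, -0.22 to 0.72 for miR-499-5p, -0.24 to 0.24 for miR-140-5p, -0.039 to 0.18 for miR-126-3p and -0.031 to 0.14 for miR-20a-5p. Lists turned direction for 7 of 154 values. The skeletal muscle list did so with the miR-1a-3p covariate (camera adjusted p = 0.932) and without control 2 (0.310), with a range of 0.0472 to 0.933 when a library was left out. The multiciliated list did so with the miR-2954 covariate (camera adjusted p = 0.97) and without H2S 1 (0.492), H2S 3 (0.933), control 1 (0.595) and control 3 (0.929), with a range of 0.31 to 0.933. The cause of these turns was not tested.

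The counts of mRNA genes at least 2-fold higher and lower were 453 and 342 with at least 50 counts, 1331 and 1177 with at least 5 counts, and 181 and 130 at a 4-fold limit, since these choices change how many genes can be counted. Other scalings gave 660 to 727 higher and 557 to 622 lower. The median of the interferon-stimulated list was 1.92 with total counts and 1.99 with at least 100 counts. The medians of all 28 lists moved by less than their intervals, although the erythrocyte median turned to -0.05 and the endothelial one to -0.0024 with at least 100 counts, and the secretory one was then at -0.028. With 5 expression bins, 11 of the 28 list percentiles moved beyond the sampling error of the random lists. Fibroblast and extracellular matrix genes, for example, went from percentile 80 to 89.3. Of 405 log2 ratios of named genes under other scalings, 10 lay outside the counting interval of the main setting. Depth limits the genes with few counts, whose ratios have wide intervals, and the single library per group limits all mRNA ratios.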

Other observations

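All tests in this part were chosen after the results were seen. Some single genes, which stand for no group, were named after their values were seen. BPIL3, a gene of the bactericidal permeability-increasing family, was 2.48-fold lower (2.45 to 2.52) in the H2S mRNA library. In the secretory list, TF, which encodes transferrin, was 2.82-fold lower (2.78 to 2.86) and PIGR, the receptor that carries secreted antibody across epithelium, had a ratio of 0.617, while MUC13 was 3.07-fold higher from 14191 against 4339 counts, and the median of the list was -0.028 among members with at least 100 counts in 1 library. The class I-like gene MICA had 9 against 57 counts. The long non-coding RNA LOC107055032 was 88.0-fold lower (55.5 to 149), from 18 against 1486 counts, and LOC107053352 was 22.3-fold higher (14.1 to 37.3). The Spearman correlation of the log2 ratio with the span of the gene in the genome, across genes that are not independent replicates, was -0.00081. It covers 10421 genes with a span, which are 87.2% of the 11957 genes with at least 100 counts in 1 library.

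The 6 small RNA libraries divide into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real division called 1 miRNA and the highest of the others 0, so 1 of the 10 divisions gave as many. For the list tests, 5 of the 10 divisions gave at least the 3 lists of the real one, and the highest of the others gave 5.

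Interferon-stimulated genes were higher in the H2S mRNA library. More leukocytes in the H2S sample would raise T cell and macrophage markers by about as much, but the joint median of these 61 markers, none of which stands in another list, was -0.27 (SD 0.79), and PTPRC, the abundant pan-leukocyte gene, had a ratio of 1.06. The state of the single H2S sample, such as an infection, cannot be told apart from an effect of the exposure, since there was 1 H2S mRNA library, and the labels do not say whether it came from a single bird or a pool. Both stay open, and an airway antiviral response in that sample is a candidate explanation that counts of viral reads would test. Exposed and control birds lived in different chambers, so a cause shared by a whole chamber cannot be told apart from the exposure either. More samples would test whether the change holds beyond that sample. Those from the same chambers would not separate chamber from exposure.

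Immunoglobulin genes were lower in the same library, with VH26L1 6.11-fold lower beside IGJ and IGLL1. Less mucosa in the sample would lower multiciliated markers by about the -2.31 of IGJ on the log2 scale, but their median was -0.20 (SD 0.29), which argues against it as the whole cause. Fewer plasma cells may account for the pattern: IRF4, PRDM1, XBP1, MZB1, TNFRSF13B and POU2AF1 had a median of -0.51 (SD 0.69), from MZB1 at 0.55 to IRF4 at -1.21. B cells or epithelium also express these 6 genes, so the test leaves this open, as it does an effect of the exposure.

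miR-2954, which is known to be higher in male than in female chickens, was at 294 CPM in H2S library 1 and 403 CPM in control library 2 against 1775 to 3200 CPM in the other 4 libraries. The same 2 libraries had miR-7b at 621 and 791 CPM, and the others 2.47 to 7.68 CPM. The values argue against the muscle share of the sample as a cause in H2S library 1, which had 1.78 times the miR-1a-3p of H2S library 2 but 0.155 times its miR-2954. For control library 2 it remains possible, as miR-1a-3p and miR-2954 were 0.172 and 0.152 times those of control library 3. The sex of the birds cannot be told apart from other causes. Both mRNA libraries are numbered 3, so neither carries the number of a small RNA library low in miR-2954. The female-specific gene HINTW had 0 counts in both mRNA libraries, which therefore cannot decide the question. The sources used here do not say whether that gene was part of the reference used for counting. Nor do they say whether mRNA and small RNA libraries of the same number come from the same sample. With miR-2954 as a covariate miR-202-5p was again called (edgeR adjusted p = 0.00202).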
